A study of Mus musculus with 2 samples.

How the data were processed

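Total RNA-seq libraries of 2 neural tubes, 1 from each of 2 pups of 1 litter at postnatal day 0, were analysed as 1 group with n = 2. Per the labels, RNA was extracted with the mirVana kit, RNA above 200 bases was kept, 10 ng entered each library, 2 spike-in references were added, and a SMARTer Ultra Low RNA Kit manual is among the protocols. Each pup gave 1 gene table and 1 transcript table. Per the file headers, these hold expected counts, posterior mean counts, TPM, posterior mean TPM, interval bounds of TPM, length and effective length, in the column names that RSEM writes. The deposited expected counts are estimated read numbers that need not be whole, and the deposited TPM values are scaled to a fixed total over all rows, spike-ins included. The percent column of the deposited transcript tables gives each transcript's share of its gene's TPM. The deposited notes name the mm10 build and the GENCODE M4 annotation. The aligner, the RSEM version and the strand setting are not given in the sources used here. In the transcript tables the effective length was the length minus 99 bases. Reads shared by near-identical genes or by overlapping genes were divided by the authors' estimation. Only some such genes are named as uncertain, so a value without that mark can still rest on shared reads.

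Gene symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, the same build as mm10, matched on gene ID without version. Of 43346 gene rows, 42462 had a symbol, and the 884 others held 0.176% of counts in each pup. Rows for 26248 tRNAs, 96 spike-ins and phiX were left out of library sizes and tests. tRNA rows held 17.7 and 6 counts, phiX rows 0, and spike-in rows 335 and 603. Total expected counts were 26917269 in pup 1 and 40004127 in pup 2. Mitochondrial genes took 6.60% and 7.51% of TPM, and protein-coding genes 94.1% and 93.8% of counts. Depth sets the precision: a gene at 0 counts could hold up to 3 counts, or 0.111 and 0.075 CPM.

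Expected counts were rounded to whole numbers. TMM factors and the common dispersion were computed with edgeR 4.0.16 in R 4.3.3 with an intercept-only design, over genes with a mean count of at least 10 (18105 genes). DESeq2 1.42.0 gave alternative size factors. Log2 ratios of CPM (counts scaled to library totals) used a prior count of 2. Genes differing at least 2-fold were counted, without a p-value, at a mean count of at least 100, and the count was set beside 100 simulated library pairs. Each list's median log2 ratio was ranked as a percentile among 10000 random lists of the same size matched on 20 bins of mean expression, over members with a mean count of at least 10 and for lists with at least 4 such members. Detection meant a TPM of at least 1. Correlations used a pseudocount of 1. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

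The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 37 lists, 24 of cell type markers and 13 of functional groups, with 418 members, of which 417 matched a row; Ahsp did not. Dlx6os1 had several rows, and the row with the higher count was used. At a TPM of at least 1 in both libraries, 339 list members were detected. Named genes were, per list, the 3 highest members by mean TPM, the lowest, and any member at a TPM of at least 1 in exactly 1 library; the 10 highest nuclear protein-coding genes; the 10 highest and 10 lowest log2 ratios at a mean count of at least 100 with TPM intervals that did not overlap; list members past 2-fold at that count; and all maturation pairs, isoform genes with differing top transcripts, and the extreme Hox groups. A few genes that the rule takes are not reported here, and a few further members were named after their values were seen.

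The 4 added lists of sensory neuron, myelin, oligodendrocyte precursor and peripheral glia genes share no member with the fixed lists. They were written after the fixed lists had been seen and before the values of their own genes were looked at. Lhfpl3 matched no row, and Pirt, of the sensory neuron list, is also among the 10 highest ratios. Their medians on the log2 scale were 0.82 (percentile 100), 0.19 (99.55), 0.01 (57.18) and 0.06 (81.49). The bounds against which these lists were judged were set down only after those values had been seen. A correction of log2 ratios for GC content, transcript length and mean expression, added after seeing the data, covered 99.1% of genes and removed 2.29% of the variance.

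The steps were tested on simulated data. For the spread between the pups and the 2-fold rule, counts of 18105 genes drawn with a coefficient of variation of 0.1 or 0.2 gave estimates of 0.100 and 0.199. Of genes changed 2-fold, 47% and 50% passed the 2-fold rule, and of genes changed 4-fold, 94% and 93%. Of unchanged genes, 0 and 230 passed. For the list differences, 4.25% of 400 random lists of 10 genes fell outside the central 95%, and a list with a planted log2 shift of 0.5 reached percentile 99.97. The lists tested were random, as were those they were ranked against. The 4.25% is therefore not an error rate for lists of genes regulated together. Alternatives were other scalings (DESeq2, total count, spike-in totals), count and TPM minimums, prior counts and pseudocounts, posterior mean values, and each pup left out.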

Results

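Total RNA was sequenced from the neural tube of 2 newborn mouse pups of the B6NCrl strain at postnatal day 0. The labels give the tissue as the neural tube, the structure that forms the brain and spinal cord, and name 1 tube per pup. Both pups came from 1 litter, so the series holds 1 group with n = 2 and no contrast between conditions. The libraries held 26916916 expected counts on gene rows in pup 1 and 40003518 in pup 2, a depth ratio of 1.49. Levels are given as TPM, the length-scaled abundance in the deposited tables, as the mean ± SD over the 2 pups unless each pup is named. Differences between the pups rest on 1 library each, so they have no replicate check, and no p-value was computed. Log2 ratios are pup 2 minus pup 1 after TMM scaling, and are relative to the bulk of genes. Spike-in totals as the scale would shift every log2 ratio by -0.29, with -0.10 and -0.49 at the ends of the 95% counting interval of the spike-in ratio. Intervals and floors cover counting error only. A count of 0 allows up to 0.111 CPM (counts scaled to library totals) in pup 1 and 0.075 in pup 2.

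Cytoskeletal genes led the nuclear protein-coding transcriptome. Tuba1a, an alpha-tubulin of growing neurons, reached 8176 ± 855 TPM (chromosome 15, 98949837 to 98953703, GRCm38), ahead of Actb, beta-actin, at 5298 ± 399. Ppia, cyclophilin A, followed at 4391 ± 324, and the actin-binding thymosins Tmsb10 and Tmsb4x stood at 4224 ± 140 and 3699 ± 407. The 10 highest also included Ftl1, ferritin light chain, at 3379.5 ± 177, Apoe, a lipid carrier made by astrocytes, at 3305 ± 41.9, Ubb, ubiquitin, at 3134 ± 6.63, and Actg1, gamma-actin, at 2736 ± 155. At a TPM of at least 1 in both libraries, 15386 of 43346 gene rows were detected, 13698 of them protein-coding. A further 595 genes reached that level only in pup 1 and 483 only in pup 2.

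Neuronal genes were abundant. All 12 of 12 pan-neuronal genes were detected, with Gap43, a growth cone protein, at 1171 ± 136 TPM, Stmn2, a microtubule regulator, at 1108 ± 16.7 and Tubb3, neuronal beta-tubulin, at 1005 ± 127. The lowest member, the RNA-binding protein gene Elavl3, was at 46.6 ± 7.5. Of the motor neuron list 10 of 10 were detected, led by Chodl at 60.7 ± 3.58, the vesicular acetylcholine transporter Slc18a3 at 41.6 ± 1.41 and the GDNF receptor Ret at 19.4 ± 0.658, while the homeobox gene Mnx1 was lowest at 1.29 ± 0.148. Isl2, another motor and sensory neuron homeobox gene, was 2.56-fold higher in pup 2 (3.57 and 8.9 TPM). Slc18a3 lies inside the annotated span of Chat on the same strand, so how reads were split between them is uncertain. In the glutamatergic list 7 of 9 were detected, and the neuropeptide genes Tac1 and Cck stood at 223 ± 21 and 120.3 ± 2.72. The vesicular transporter Slc17a6 was at 101 ± 6.94, Slc17a8 reached a TPM of 1 only in pup 1 (1.02 and 0.99), and Slc17a7 was lowest at 0.59 ± 0.552. All 10 of 10 inhibitory neuron genes were detected, with neuropeptide Y (Npy) at 273 ± 29.4, the GABA-synthesising enzymes Gad1 and Gad2 at 95.4 ± 9.73 and 33.1 ± 3.27, and the homeobox gene Gbx1 lowest at 8.62 ± 0.53.

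Interneuron transcription factors had list medians of 1.12 TPM for ventral and 2.88 for dorsal types, against 294 for pan-neuronal genes. In the ventral list 5 of 9 were detected, among them Gata3 at 4.32 ± 0.0141 TPM and Sox14 at 4.14 ± 0.198, with Sim1 lowest at 0.14 ± 0.0283. In the dorsal list 5 of 7 were detected, led by Prrxl1 at 77.9 ± 4.46, Pou4f1 at 29.2 ± 0.0636 and Lbx1 at 18 ± 2.11, with Barhl2 lowest at 0.705 ± 0.106. Progenitor genes included Fabp7, a radial glia fatty acid binding protein, at 2194 ± 92.3, the intermediate filament Vim at 325 ± 5.7 and the Notch target Hes5 at 102 ± 9.65. Of that list 11 of 12 were detected, and Sox1 reached a TPM of 1 only in pup 2 (0.86 and 1.11). All 12 of 12 cell cycle genes were detected, from Pcna, the DNA polymerase clamp, at 75.1 ± 1.75, Cdk1 at 34.2 ± 5.07 and Birc5 at 16 ± 0.813 down to the checkpoint kinase Bub1 at 2.23 ± 0.389.

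Glial genes were led by astrocyte genes, with a list median of 133 TPM. The 12 of 12 detected astrocyte genes were led by Apoe, the glycolytic enzyme Aldoc at 930 ± 20.5 TPM and the GABA transporter Slc6a11 at 225 ± 18.7, and the glutamate transporter Slc1a2 was lowest at 30.1 ± 1.61. Oligodendrocyte precursor genes were detected for 8 of 8, with the proteoglycan Bcan at 254 ± 34.3, the lineage factor Olig1 at 160.5 ± 8.09, Ptprz1 at 35.5 ± 2.62 and Cspg4 lowest at 7.07 ± 1.02. Of the myelinating oligodendrocyte list 10 of 12 were detected, including Mbp, myelin basic protein, at 273 ± 127 and Cnp at 163 ± 32.2. Mog, a late myelin glycoprotein, reached a TPM of 1 only in pup 2 (0.72 and 1.64), and Opalin was lowest at 0.030 ± 0.0424. The ependymal and floor plate list had 7 of 10 detected, led by Spon1 at 47.5 ± 3.58, the guidance cue Ntn1 at 17.5 ± 0.863 and Rarres2 at 16.5 ± 0.714. Shh, the floor plate morphogen, reached it only in pup 2 (0.99 and 1.25), and Sspo was lowest at 0.18 ± 0.0707. All 12 of 12 microglia genes were detected, with the complement gene C1qb at 89.8 ± 7.87 and C1qa at 60.7 ± 0.827, and Siglech lowest at 3.4 ± 0.976.

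Genes of vessels, meninges and neighbouring tissues were also measured. Endothelial genes were detected for 9 of 10, with the tight junction gene Cldn5 at 117 ± 18.9 TPM, Ly6c1 at 42.2 ± 10.5, Esam at 33.5 ± 3.46 and Slco1a4 at or above a TPM of 1 only in pup 2 (0.73 and 1.78). Pericyte and smooth muscle genes were detected for 7 of 8, from Rgs5 at 12.3 ± 2.31, Acta2 at 8.83 ± 1.7 and Kcnj8 at 7.97 ± 1.83 to Myh11 at 0.42 ± 0.0283. All 11 of 11 meningeal and fibroblast genes were detected, led by Ptgds, prostaglandin D synthase, at 1556 ± 897, Igf2 at 333 ± 72.5 and the collagen gene Col1a1 at 209 ± 33.4, with Twist1 lowest at 1.91 ± 0.707. Schwann cell genes were detected for 6 of 7, with the peripheral myelin gene Pmp22 at 104 ± 3.18, Prx at 10.5 ± 2.09, and Cdh19 at or above a TPM of 1 only in pup 2 (0.87 and 1.31). Among dorsal root ganglion genes 4 of 9 were detected, with the neurofilament Prph at 111 ± 22.4, the peptide gene Calca at 78 ± 20.5 and the sodium channel Scn9a at 8.6 ± 0.0495, and Trpv1 lowest at 0.35 ± 0.184. In pup 2 alone 7 of the 9 were detected. Skeletal muscle genes were detected for 9 of 12, led by Acta1 at 34.2 ± 0.0707, Myl1 at 8.98 ± 0.919 and Mylpf at 7.82 ± 2.09, with Myog lowest at 0.015 ± 0.0212. Cartilage and bone genes were detected for 5 of 10, led by Ibsp at 7.09 ± 1.17, Col2a1 at 2.73 ± 0.912 and Col9a1 at 2.0 ± 0.099. Comp (1.1 and 0.83) and Col10a1 (1.15 and 0.57) reached it only in pup 1, and Matn1 and Sp7 were lowest at 0.455 ± 0.0495 and 0.455 ± 0.0636. Globin genes were high, with Hba-a2 at 1495 ± 294, Hbb-bs at 848 ± 137 and Hba-a1 at 621 ± 129, while 5 of 9 erythroid genes were detected and Hemgn was lowest at 0.015 ± 0.0212. The Hba-a1 and Hba-a2 values are uncertain, since near-identical copies share reads. Leukocyte genes were detected for 5 of 9, with Lyz2 at 44.9 ± 15.5, the neutrophil genes S100a8 at 17.7 ± 7.67 and S100a9 at 7.95 ± 2.9, Ngp at or above a TPM of 1 only in pup 2 (0.49 and 1.78) and Elane lowest at 0.025 ± 0.0354.

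Hox genes, which mark position along the body axis, were detected for 31 of 39 members. The highest single genes were Hoxa7 at 105 ± 29.2 TPM, Hoxb6 at 89.2 ± 7.14 and Hoxd10 at 84.1 ± 29.6, and the lowest were Hoxa13 and Hoxb13 at 0 counts in both. Summed by paralog group, group 10 was highest at 207 ± 73.3 TPM and group 13 lowest at 1.61 ± 1.97. Without pup 1 the highest group was 7, at 201 TPM in pup 2. Hoxd1 (0.36 and 1.07) reached a TPM of 1 only in pup 2, and Hoxc13 (2.85 and 0.14) only in pup 1. Forebrain and midbrain genes were detected for 2 of 11 members. Neurod6 was at 31 ± 3.01, while Dlx5 was at 0.40 ± 0.127 and Otx1, Otx2 and Nkx2-1 were at 0 counts in both libraries. Hindbrain and monoaminergic genes were detected for 2 of 8, with Phox2a at 1.94 ± 0.134, Th, tyrosine hydroxylase, at 1.49 ± 0.318, Slc6a4 at 0.715 ± 0.177 and Slc6a2 lowest at 0.035 ± 0.0354.

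**Figure D1:**
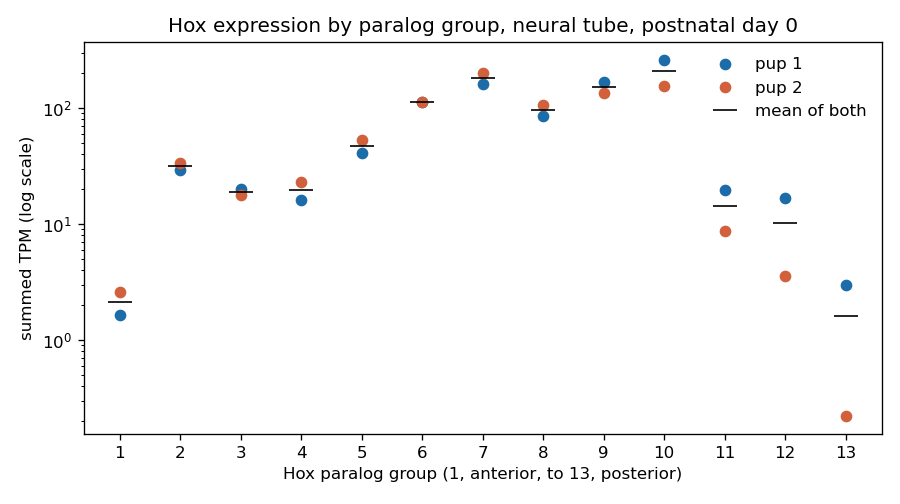
Summed TPM of the Hox genes of each paralog group (x axis, 1 to 13) on a log scale, with 1 point per pup and a bar at the mean. Group 10 stood at 259 TPM in pup 1 and 155 in pup 2, group 12 at 16.7 and 3.57, and group 13 at 3.0 and 0.22.

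Among functional lists, 13 of 14 axon guidance genes were detected, with Efnb3 at 115 ± 10.0 TPM, Robo2 at 38.4 ± 5.11 and Nrp1 at 35.6 ± 0.198, and the commissural receptor Robo3 at or above a TPM of 1 only in pup 1 (1.0 and 0.62). All 16 of 16 synapse genes were detected, led by Syp, synaptophysin, at 266 ± 28.3, the AMPA receptor subunit Gria2 at 149 ± 16.9 and Syn1 at 91.7 ± 5.34, with Glra1 lowest at 5.13 ± 0.0707. Immediate early genes were detected for 9 of 11, with Jun at 55.4 ± 0.325, Ier2 at 17.4 ± 0.813, Dusp1 at 13.6 ± 1.03 and Fosb lowest at 0.13 ± 0.0424. The hypoxia and glycolysis list had 10 of 10 detected, with Ldha at 544 ± 5.52, Pgk1 at 213 ± 5.13, Bnip3 at 138 ± 11 and Adm lowest at 2.0 ± 0.0141. Interferon response genes were detected for 7 of 8, with Bst2 at 21.4 ± 1.82, Isg15 at 5.43 ± 0.311 and Rsad2 lowest at 0.80 ± 0.099. All 13 of 13 imprinted genes were detected, with Nnat at 2656 ± 161, Snrpn at 1046 ± 71.1, Ndn at 909.5 ± 65.2 and Peg10 lowest at 4.1 ± 0.976. The Y-linked genes Eif2s3y, Ddx3y and Uty stood at 63.4 ± 7.25, 27.5 ± 0.184 and 9.52 ± 1.07, 4 of 6 genes of the sex-chromosome list were detected, and Xist was lowest at 0.010 and 0.010 TPM. The labels record that sex was not collected.

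RNA classes outside nuclear mRNA were measured too. All 13 of 13 mitochondrial mRNAs were detected, with mt-Atp6 at 14400 ± 309 TPM, mt-Atp8 at 10514 ± 1366, mt-Cytb at 5555 ± 201 and mt-Nd4l lowest at 235 ± 39.5. Nuclear copies share reads with these genes, so the mt-Co3 values of 2038 in pup 1 and 3819 in pup 2 are uncertain. All 16 of 16 ribosomal protein genes were detected, from Rplp1 at 967 ± 9.14, Rps18 at 722 ± 12.2 and Rps2 at 688 ± 6.0 to Rpl5 at 38.8 ± 4.23. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were detected for 7 of 14, led by Hist1h4d at 77.1 ± 5.01, Hist1h1e at 18 ± 2.95 and Hist1h2ae at 14.5 ± 1.6. Hist1h4h (0.63 and 3.11), Hist1h2bj (0.42 and 1.9) and Hist1h1d (0.83 and 1.03) reached a TPM of 1 only in pup 2, and Hist1h2ag and Hist1h3c were at 0 counts in both. Of the small non-polyadenylated RNAs 5 of 8 were detected, with the signal recognition particle RNA genes Rn7s1 and Rn7s2 at 16157 ± 22.9 and 16157 ± 24.2, which are near-identical copies and uncertain singly, and Rn7sk at 407 ± 30.0. Terc reached it only in pup 1 (1.07 and 0.93), and Rny1 and Rny3 were at 0 counts in both. How cDNA was primed was not established here, and only RNA above 200 bases was kept. The TPM of RNAs without a poly(A) tail, and of short RNAs, may therefore not reflect their abundance. Long non-coding RNAs were detected for 9 of 10, with Malat1 at 6180.2 ± 13.8, Meg3 at 1888 ± 464, Snhg11 at 631 ± 106 and Dlx6os1 lowest at 0.010 ± 0.

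In 10 of 11 gene pairs fixed as an early and a late partner or as transmitter systems, the first partner was higher in both libraries. The NMDA receptor pair Grin2b to Grin2a had a TPM ratio of 3.58 ± 0.985, and the glycine receptor pair Glra2 to Glra1 7.22 ± 0.681. The sodium channel pair Scn3a to Scn8a stood at 1.29 ± 0.333. Among neurofilaments, Ina to Nefh was 4.07 ± 0.498 and Nefl to Nefh 17.4 ± 1.33, and the tubulin pair Tubb2b to Tubb4a was 2.36 ± 0.164. Nefl lies inside the annotated span of Nefm on the other strand, and no strand setting was given, so the Nefl ratio is uncertain. The precursor gene Pdgfra exceeded the myelin gene Mog 16.1 ± 8.63 times, at 22.2 in pup 1 and 9.98 in pup 2, and Gad2 exceeded the glycine transporter Slc6a5 2.04 ± 0.453 times. The ratio of Slc17a6 to Slc17a7 was 531 in pup 1 and 98.3 in pup 2, with 10 Slc17a7 counts in pup 1. The exception was the chloride transporter pair, where the importer Slc12a2 was at 0.104 ± 0.0223 of the exporter Slc12a5. With expected counts not divided by length, Grin2b to Grin2a was 10.2, Scn3a to Scn8a 2.14, Pdgfra to Mog 64.5 and Gad2 to Slc6a5 1.15, so the size of these ratios depends on the unit.

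Most genes used the same leading transcript in both pups. Among the 22 genes fixed for isoforms, 21 had several transcripts, and 19 of these had the same top transcript in both, such as Snap25-201 with 98.4% ± 0.191 of Snap25. The shared top transcripts of Agrn, Kif1b and Fn1 were annotated as retained introns. The AMPA receptor gene Gria2 was led narrowly in pup 1 by Gria2-206, also annotated as a retained intron. It held 41.6%, against 40.7% for the protein-coding Gria2-202. In pup 2 Gria2-202 led with 46.1%, against 38.0% for Gria2-206. Map2, a dendritic microtubule protein, was led by Map2-201 in pup 1, at 30.7% against 24.1% for Map2-204. In pup 2 Map2-204 led narrowly, at 25.6% against 23.4%. Over 8481 genes with several transcripts and a mean TPM of at least 5, 91.8% shared their top transcript. The genes are not independent replicates, so this share describes these 2 libraries only.

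The genes with the 10 highest and 10 lowest ratios included sensory ganglion, myelin and Hox genes. Avil, a sensory neuron actin regulator (chromosome 10, 127000709 to 127020994), was 12-fold higher in pup 2, the ATP receptor P2rx3 (chromosome 2, 84998583 to 85037462) 8.31-fold and the sodium channel Scn10a 6.9-fold. Avil, P2rx3 and Scn10a had a TPM below 1 in pup 1, at 0.70, 0.58 and 0.19. Mobp, a myelin protein (chromosome 9, 120149707 to 120181484), was 5.44-fold higher in pup 2 (2.27 and 12.8 TPM). Hoxc12 (chromosome 15, 102936757 to 102938609) was 4.36-fold lower in pup 2, Hoxd11 3.04-fold and Hoxc11 2.73-fold. The 10 highest ratios also included Xlr3b at 15.9-fold, which has near-identical X-linked copies and is uncertain, Trarg1 at 4.58-fold, the tetraspanin Tspan8 at 4.54-fold, Pirt, a sensory channel regulator, at 4.19-fold, and a gene row without a symbol. That row was listed at 0 and 536.75 counts, but its deposited posterior mean counts were 65.0 and 560.5, so its value is uncertain and no fold is given. The other genes of the 10 lowest ratios were Hoxa11os at -1.20, Kansl2-ps at -1.29, Gm28309 at -0.97, Gm20605 at -0.92, Gm15725 at -0.90, Gm9800 at -0.85 and B830012L14Rik at -0.85 on the log2 scale. Hoxa11os is antisense to Hoxa11, and no strand setting was given, so its reads cannot be assigned to 1 strand. Hoxd11 and Gm28309 overlap on the same strand, so how reads were split between them is uncertain. Kansl2-ps, Gm15725 and Gm9800 are annotated as processed pseudogenes, and their values are uncertain too.

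Counted together, 64 of 13545 genes with a mean expected count of at least 100 differed at least 2-fold, 56 higher and 8 lower in pup 2. Unlike the ranking above, this count does not ask that TPM intervals lie apart. It therefore holds genes whose intervals overlap, such as Tom1. In 100 simulated library pairs, Poisson sampling gave 0 such genes, and Poisson sampling with the common dispersion gave at most 2. Every gene was simulated with 1 dispersion, estimated from these 2 libraries, so genes that vary more than others are not represented. In the simulated test at a coefficient of variation of 0.2, 230 unchanged genes passed the rule. The simulation therefore does not show that the 64 genes exceed ordinary variation between pups. With spike-in totals as the library scale, 58 genes differed at least 2-fold, 30 higher and 28 lower. Without the minimum on counts 1987 genes passed, 977 higher and 1010 lower. The median absolute log2 ratio was 0.11, and 85.8% of genes lay within 1.2-fold. Across all gene rows, Pearson r of log2(TPM + 1) between the pups was 0.995 and Spearman rho 0.953. These are correlations across genes, which are not independent replicates. The biological coefficient of variation was 0.0955, and 0.179 with the spike-in scale. The chi-square of the counts was 12.6 per degree of freedom over 18105 genes, so the files do not hold 1 set of counts given again. The labels name them as 2 pups, and the counts cannot tell 2 animals from 2 library preparations.

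As groups, dorsal root ganglion genes were higher in pup 2 for 9 of 9 members, with a median log2 ratio of 1.98 (percentile 100 of matched random lists). That median was 0.57 as a ratio of TPM with a pseudocount of 1, which damps genes with low TPM, and 2.79 over members with a mean count of at least 50, both at percentile 100. The lowest member, Scn9a at 0.07, would turn negative with the spike-in scale. Myelinating oligodendrocyte genes followed with 10 of 11 members higher and a median of 1.02 (percentile 100). Cldn11 was at 40.9 and 83.2 TPM, Mag, a myelin adhesion protein, at 16 and 31.3 and Enpp6, a marker of newly formed oligodendrocytes, at 2.84 and 10.3. Mal was the exception at -0.23 on the log2 scale. Leukocyte genes had a median of 0.81 (percentile 100), with 6 of 7 higher, among them Lyz2 at 0.79. All 11 meningeal and fibroblast genes were higher in pup 2, Col3a1 the least at 0.19, which turns negative with the spike-in scale, with a median of 0.41 (percentile 100) and Ptgds at 1.32. Replication-dependent histones, whose measured levels may not reflect abundance, stood at 0.39 (percentile 98.54), with 9 of 10 higher. Also above the central range, but with medians that turn negative with the spike-in scale, were skeletal muscle (0.26, 98), motor neurons (0.25, 99.96), mitochondrial mRNAs (0.14, 99.91), oligodendrocyte precursors (0.12, 98.54) and ribosomal proteins (0.09, 97.71). The members higher in pup 2 were 10 of 11, 9 of 10, 11 of 13, 5 of 8 and 15 of 16 in that order. Motor neuron members ranged from -0.06 for Lhx4 to 1.35 for Isl2, which is also a sensory neuron gene. Mmp9 and Isl1 stood at 0.63 and 0.59, while Chat, at 0.02, and Ret, at 0.004, barely moved. Libraries of whole tissue cannot tell in which cells Isl2, Mmp9 and Isl1 were higher, so the call is not specific to motor neurons. At a shift of -0.10 only the ribosomal protein median of the 16 lists outside the range turns negative, and at -0.49 the meningeal and histone medians turn negative too.

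Below the central range lay erythroid genes, with a median log2 ratio of -0.33 (percentile 0.02) and Hbb-bs at -0.26, all 7 measured members being lower in pup 2. Long non-coding RNAs stood at -0.32 (percentile 0), with 6 of 9 lower, among them Meg3 at -0.46. Pericyte and smooth muscle genes stood at -0.28 (percentile 0.13), 6 of 8 of them lower, and axon guidance genes at -0.16 (percentile 0), 12 of 14 of them lower. Synapse genes at -0.10 (0.81), with 12 of 16 lower, and pan-neuronal genes at -0.09 (1.39), with 9 of 12 lower, were also below it. The whole Hox list had a median of 0.02 (percentile 68.53), but its members went both ways. Of groups 1 to 8, 17 of 23 genes were higher in pup 2, with a median of 0.21 that turns negative with the spike-in scale. Hoxc5, Hoxc8 and Hoxc6 were 3.58-, 2.34- and 2.09-fold higher in pup 2, and 11 of 12 genes of groups 9 to 13 were lower. The annotated span of Hoxc5 contains Hoxc6, Hoxc8 and Hoxc9, and how reads were split among them is uncertain. Of the 36 lists with at least 4 measured members, 10 lay above the central 95% of matched random lists, 6 below it and 20 inside. These percentiles describe these 2 libraries only. Members of a fixed list can be regulated together, which the random lists do not reproduce. The calls of skeletal muscle, synapse, oligodendrocyte precursor and ribosomal protein genes were lost under another setting.

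**Figure D2:**
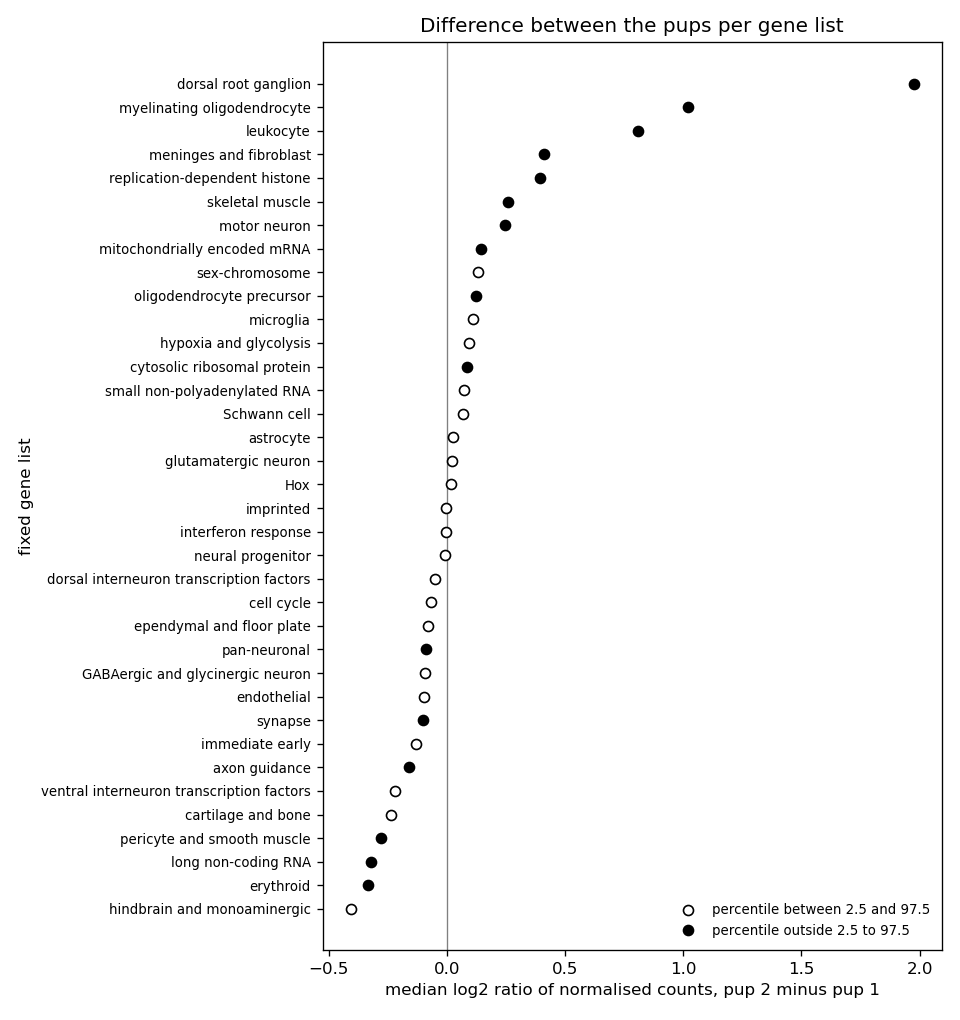
Median log2 ratio of normalised counts, pup 2 minus pup 1 (x axis), for each of the 36 fixed lists with at least 4 measured members (y axis). Filled points lie outside the central 95% of matched random lists, and dorsal root ganglion (1.98) and myelinating oligodendrocyte (1.02) genes lie farthest to the right.

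The remaining lists lay inside the central range, and those with a positive median turn negative at the spike-in shift of -0.29. Microglia genes had a median log2 ratio of 0.11 (percentile 97.43), hypoxia and glycolysis genes 0.09 (92.59), small non-polyadenylated RNAs 0.07 (77.44), Schwann cell genes 0.07 (79.75), astrocyte genes 0.03 (66.65) and glutamatergic neuron genes 0.02 (61.99). Imprinted genes stood at -0.00 (46.3), interferon response genes at -0.00 (49.92), progenitor genes at -0.01 (44.63), dorsal interneuron factors at -0.05 (31.29) and cell cycle genes at -0.07 (14.68). Ependymal and floor plate genes stood at -0.08 (21.5), inhibitory neuron genes at -0.09 (4.79), endothelial genes at -0.10 (6.66), immediate early genes at -0.13 (5.595) and ventral interneuron factors at -0.22 (5.16). Cartilage and bone genes were at -0.23 (4.48), hindbrain and monoaminergic genes at -0.41 (4.92) and sex-chromosome genes at 0.13 (92.74). Forebrain and midbrain genes had 3 measured members and no percentile. The mean log2 ratio had the opposite sign to the median for progenitor (0.05), endothelial (0.07), Schwann cell (-0.0089), Hox (-0.09) and imprinted genes (0.05).

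Spike-in RNAs held 335 counts in pup 1 and 603 in pup 2, or 0.00124% and 0.00151% of all expected counts (95% exact Clopper-Pearson intervals 0.00111 to 0.00139 and 0.00139 to 0.00163). Of 96 spike-in rows, 20 had counts in both libraries. Over the 28 rows with counts in either library, Pearson r of log2(count + 1) was 0.928 and Spearman rho 0.869.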

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

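The tests of Hox, dorsal root ganglion and myelin genes were chosen, and their bounds set, after the results were seen, while the members of the added lists were chosen before their own values were looked at. Expected counts on tRNA rows, which lie outside the main measurement, summed to 17.7 in pup 1 and 6 in pup 2, over 7 and 4 of 26248 rows. The sums stand here only because they exceed 3 counts, the limit for a count of 0, as any few stray reads over so many rows would, so they say nothing about tRNA levels.

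Hox genes of paralog groups 1 to 8 had a median log2 ratio of 0.21 and those of groups 9 to 13 a median of -0.63. A difference in library scale or depth moves every gene alike and so cannot set these medians 0.84 apart, though the spike-in scale turns the first one negative at a shift of -0.29 and not at -0.10, the low end of its counting interval. After correction for GC content, length and expression the Spearman rho of the ratio with the paralog number across genes was -0.67, against -0.67 before, so those properties do not account for the trend. A candidate explanation is that the tissue pieces reached different distances along the body axis; each of the 4 clusters had the trend, the weakest Hoxa at rho -0.53, but these are the genes that showed the pattern, so this restates it and does not support the explanation. The labels do not give the extent of the tissue, so that explanation and a difference in Hox expression between the pups stay open, and no biological explanation was tested.

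Dorsal root ganglion genes were higher in pup 2. Counting error at low depth is argued against by 8 of 9 members whose 95% counting interval of the fold lay above 1, for example 8.92 to 18.2 for Avil; Scn9a, at 0.959 to 1.14, was the exception. Sensory ganglion tissue left on the neural tube is a candidate explanation. The second list of sensory neuron genes had a median log2 ratio of 0.82, with 10 of 13 members higher. Its members ranged from -0.82 to 3.72. That list can show more sensory neuron RNA in pup 2, but not where it came from. The most abundant genes of the fixed list, Prph and Calca, were higher by only 1.40 and 1.53 times by counts. Schwann cell genes, which ganglia and roots also carry, did not move as a list with the sensory neuron genes. Their median was 0.07, with members from -0.49 to 0.57. The second list of peripheral glia genes had a median of 0.06 (percentile 81.49), with 7 of 10 members higher and a range from -0.22 to 1.87. At a TPM of at least 1 in both pups the tissue held 4 of 9 genes of the fixed ganglion list and 4 of 18 of the second sensory neuron list. In pup 2 alone these were 7 of 9 and 5 of 18. Genes that are low in pup 1 cannot enter the count for both pups. No biological explanation was tested.

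Myelinating oligodendrocyte genes had a median log2 ratio of 1.02. Peripheral myelin from Schwann cells needs the Schwann cell list to move about as far, and its median was 0.0671. More cells of the whole oligodendrocyte lineage need precursor genes to move about as far too, and while the fixed precursor list was higher in pup 2, at a median of 0.12 (percentile 98.54), and the second at 0.0139, both lay below the myelin median by more than the median absolute deviations of 0.127, 0.102 and 0.304. A larger pool of myelinating oligodendrocytes carrying all their genes needs the second myelin list to follow, and its median was 0.19 with 11 of 16 members higher, above the central range of random lists but short of the fixed list, and negative at the spike-in shift of -0.29, as are the Schwann cell and both precursor medians. Members of the second myelin list ranged from -0.31 to 1.42, and the bound was set after these values were seen. A larger pool of myelinating oligodendrocytes therefore stays open. Also open are a shift in some myelin genes, such as later maturation in pup 2, and a different part of the body axis being taken. The latter may go with the Hox trend. Neither the shift nor the part taken was tested.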

How the results depend on the processing

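The correction for GC content, length and expression and the Hox trend settings were chosen after seeing the data. No paired analysis was possible because the series holds 1 group. Genes detected in the single remaining library were 15869 without pup 1 and 15981 without pup 2, against 15386 in both libraries. List members detected were 353 and 345 in that order, against 339 in both. Pairs with the first partner higher stayed at 10 with either pup left out. The highest Hox paralog group was 7 without pup 1 and 10 without pup 2. Single ratios moved by more than their spread for 11 values, among them Grin2b to Grin2a (3.58 to 10.2) and Pdgfra to Mog (16.1 to 64.5) with counts not divided by length, and Pdgfra to Mog was 9.98 to 22.2 with each pup left out. The dorsal root ganglion median, 1.98, was 0.57 by TPM with a pseudocount of 1 and 2.79 at a mean count of at least 50. Of the 15 others outside the central range, by that TPM ratio these medians moved over 1.5 times on the log2 scale: pan-neuronal to -0.15, motor neuron 0.16, oligodendrocyte precursor 0.05, skeletal muscle 0.11, axon guidance -0.25, mitochondrial mRNA 0.07, ribosomal protein 0.0193 and histone 0.22. With the GC correction axon guidance moved to -0.11, mitochondrial mRNA 0.23, ribosomal protein 0.0382 and long non-coding RNA -0.21; the causes were not tested. The count of genes past 2-fold went from 64 to 102 with a mean count of at least 50 and to 1987 with no minimum, because more genes with few counts entered. The Spearman rho across genes went from 0.953 to 0.988 over genes with a mean TPM of at least 1 and to 0.987 with posterior mean TPM; the cause was not tested for the latter. With the spike-in scale the coefficient of variation went from 0.0955 to 0.179 and 13 of 36 list medians turned negative, as that scale shifts all ratios. The 6 outside the central range in either setting were motor neuron at -0.0432, oligodendrocyte precursor -0.17, microglia -0.18, skeletal muscle -0.0326, mitochondrial mRNA -0.15 and ribosomal protein -0.21. Of the 16 lists outside it, 1 changed sign at the low end of the spike-in ratio's counting interval and 7 at the high end, computed after seeing the data. The spike-in share went from 0.00138% to 0.00306% as a share of TPM, and the share of genes with the same top transcript from 91.8% to 89.85% at a mean TPM of at least 1; the cause was not tested. The Hox trend, -0.67 over 35 genes, was -0.53 for Hoxa, -0.88 for Hoxc and -0.89 for Hoxd alone, and kept its sign in all settings run. List calls were lost under at least 1 setting for 4 lists (oligodendrocyte precursor, skeletal muscle, synapse and ribosomal protein) and gained for 3 (inhibitory neuron, microglia, and cartilage and bone). Depth limits genes at or under 3 counts.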

Other observations

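The genes named here were chosen after their values were seen, and each was at least 2-fold higher in pup 2 by TMM-scaled counts, with log2 ratios from 1.00 for Foxc2 to 1.64 for Acp5. Spp1, osteopontin, had 24.4 TPM in pup 1 and 72.5 in pup 2, Acp5, tartrate-resistant acid phosphatase, 3.71 and 11.2, Ctsk, the protease cathepsin K, 13 and 26 and Hmox1, a heme-degrading enzyme, 13.5 and 40.3. The forkhead transcription factor gene Foxc2 had 2.96 and 5.69 TPM and Foxd1 1.2 and 3.57. Wnt6, a secreted signalling protein gene, had 7.77 and 14.9 TPM, and the matrix gene Ogn, osteoglycin, 8.03 and 15.4. With the spike-in scale, which shifts log2 ratios by -0.29, Foxc2, Ogn, Wnt6 and Ctsk fall under 2-fold.

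Tom1 was listed at 0 expected counts in pup 1 and 488 in pup 2, but its deposited TPM intervals overlap between the pups, so it was not among the genes ranked by ratio.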
